A study of Arabidopsis thaliana with 6 samples.

How the data were processed

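RNA sequencing was done on developing seeds of Arabidopsis thaliana, strain Columbia-0, from wild type (WT) and from the lines ar21 and i4g1, with 2 biological replicates per line and 6 libraries in all. Per the labels, plants grew at 22 °C by day and 17 °C by night with 16 hours of light and 8 hours of dark, flowers on primary shoots were tagged, and seeds were dissected from siliques 13 days after flowering. The extraction text of the labels gives 12 to 13 days. Total RNA went into libraries made with a kit whose usual protocol selects poly(A) RNA and does not mark the strand. The labels say nothing of batches or dates, and how the strand was treated in counting is not given in the sources used here.

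The deposited table holds, for each library and locus, a signal that is a read count divided by 1 size factor per library (a normalised count). Per the submitters' processing notes, the authors used STAR 2.4.0j, StringTie 1.0.3, HTSeq 0.6.0 and DESeq2 1.12.4 with the genome build TAIR10. The notes give no parameters and no roles for these tools. The table has 34001 merged loci, of which 33765 carry a TAIR locus and 236 an assembled transcript, and 33055 matched the TAIR10.1 annotation used here. The 6 value columns were assigned to the samples by their names, and no value column was left over. Every nonzero value of a library was a whole multiple of 1 step of that library (100.0% within a tolerance of 0.001). Whole reads were therefore recovered for 5 libraries by dividing by the step. For ar21 replicate 1 the step lay too close to 1 to be told from rounding. Its values therefore entered the tests of genes and lists only as normalised counts. The median log2 ratio of a library to the geometric mean was 0.01 in each of the 6 libraries over 17776 loci above 0 in all, as a median-of-ratios scaling gives.

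Recovered reads per library were 5187867 in WT replicate 1, 3418773 in WT replicate 2, 6071914 in ar21 replicate 2, 4972656 in i4g1 replicate 1 and 8435759 in i4g1 replicate 2. Dividing by the step gave 5078206 for ar21 replicate 1. Without the nuclear 18S rRNA locus (AT3G41768, TAIR10.1 chromosome 3, 14197677 to 14199484, + strand) the totals were 3070006, 1344947, 3556647, 4872053, 4401061 and 8106414 for WT 1, WT 2, ar21 1, ar21 2, i4g1 1 and i4g1 2. Intervals for shares of reads are exact (Clopper-Pearson) 95% intervals and cover counting error only. On average over genes, replicates differed beyond that error. The mean chi-square per gene between replicates, over genes with at least 50 reads, was 5.50 in WT, 3.81 in ar21 and 11.3 in i4g1. The medians were 0.68, 0.73 and 1.42, so a part of the genes raised the means. Here the values of ar21 replicate 1 divided by the step were taken as reads.

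The name i4g1 is read as a mutant of eIFiso4G1 (AT5G57870), and ar21 as a line with a mutation in the same gene from a study of seed oil. This reading comes from knowledge of the study, not from the labels. Before the data were examined, the samples, comparisons, tests, gene lists, the rule for named genes and most alternative settings were fixed. Values were tested as log2(normalised count + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 6 libraries in 1 fit, an intensity trend in the empirical Bayes step and a mean of at least 10 over all libraries (15591 loci). P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. The comparisons were ar21 against WT, i4g1 against WT, ar21 against i4g1 as the test of the difference between the mutants, and the mean of both mutants against WT. Levels are given as mean normalised counts ± SD over 2 libraries (n = 2), and log2 fold changes ± SE from limma. "Adjusted over the list alone" means that the Benjamini-Hochberg step was applied to the members of a list only.

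Gene lists, 20 in number and 308 members in all, were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists. Beside it, camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run on the same fit. The estimated correlation, and the test that uses it, rest on the 3 residual degrees of freedom of the fit. That test has little power here, so a list that fails it is not read as unchanged. The lists were eIF4F and poly(A)-binding proteins, fatty acid synthesis, triacylglycerol assembly and oil bodies, seed maturation regulators, seed storage proteins, late embryogenesis and desiccation, abscisic acid synthesis and signalling, sucrose breakdown and plastid glycolysis, starch metabolism, sugar starvation and SnRK1 marker genes, lipid breakdown and glyoxylate cycle, photosynthesis and chlorophyll, unfolded protein response and ER folding, heat shock proteins, cytosolic ribosomal proteins, and defence and salicylic acid. Another 4 lists held markers of cell types: seed coat flavonoid, seed coat mucilage, endosperm, and shoot tissue outside the seed. Of the members, 1 was dropped because its locus carries another symbol in the reference, 3 had no value, 18 had several values for 1 locus and 21 had a mean under 1. Entries of loci listed more than once were at 0 in all libraries more often. The share was 49.6% of the entries for loci with 2 entries and 61.3% for loci with 3 or more, against 30.7% with 1. Whether such a locus had all of its entries at 0 was not counted. A value at or near 0 for such a gene, among them CRA1, is not read as absence.

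Named genes were chosen by rule: eIFiso4G1, eIFiso4G2 and eIF4G in every comparison. For each mutant against WT they were the 8 highest and 8 lowest log2 fold changes among genes that passed, with a mean of at least 50 and both mutant libraries on the same side of both WT libraries. For ar21 against i4g1 they were the 5 highest and 5 lowest, and of the genes that passed in both mutants the 5 up and 5 down with the largest smaller change. For each list, up to 4 members with the smallest p were named. Other members named in the text are given as part of the count of their list. Symbols are those of the deposited table.

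Alternatives fixed beforehand were pseudocounts of 0.5 and 5, no filter and a filter at 50, other scalings, a replicate block, only the groups compared, empirical Bayes without trend or robust, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, stricter thresholds, and leaving out each library in turn. The count tests used 5 libraries, with 1 for ar21. With a library left out or ar21 held by 1 library, the lone library is assumed to vary like the other groups. Settings chosen after seeing the data were nuclear genes only, 4 libraries without WT 2 and i4g1 2, a correction of each library's trend on transcript length and GC content, and edgeR on reads thinned to 1344947 per library. Shared WT libraries were allowed for with 100 simulations of unchanged groups, in which all lines had the same spread for a gene. Groups of 2 are too small for a test of an outlying library or of other splits of the samples. Terms of biological processes from the TAIR10.1 annotation (140 with at least 15 measured members) were tested with camera after the data had been seen.

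The workflow was tested on simulated data. The simulated counts had the mean levels and size factors of these libraries. Their dispersion was set to the same value for every gene and line and was not estimated from these libraries. In the ar21 comparison of 15591 genes, limma passed 0% of genes set to change 1.5-fold, 34% of those set to 2-fold and 100% of those set to 4-fold. It made 1 false call (1.18% of calls), and edgeR on 5 libraries passed 13% of the 2-fold genes. These shares hold for that setting and do not give the power in the data. The p adjusted by camera was 1.33e-09 for a shifted list and 0.656 for an unshifted one. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Sequence variants, strand and transcript isoforms were not analysed here, since the table gives only locus values.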

Results

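The data are normalised read counts of 34001 merged loci in developing seeds 13 days after flowering, from 2 WT, 2 ar21 and 2 i4g1 libraries of 3418773 to 8435759 reads. The most variable direction across the 6 libraries (55.3% of the variance) had both WT libraries on one side and all 4 mutant libraries on the other. Scores on it were -55.5 in WT 2, -42.4 in WT 1, 14.8 in ar21 2, 16.9 in ar21 1, 28.3 in i4g1 1 and 38.0 in i4g1 2. The rRNA share given below falls in the same order except between the ar21 libraries, so this direction does not separate line from library composition. The next direction (15.7%) parted the WT libraries from each other. Levels below are mean normalised counts ± SD with n = 2 libraries per line, and p-values are adjusted values from limma, or from camera for gene lists.

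The nuclear 18S rRNA locus AT3G41768 and organelle transcripts took a larger share of both WT libraries than of any mutant library. AT3G41768 took 40.8% and 60.7% of the reads in WT 1 and 2, 30.0% and 19.8% in ar21 1 and 2, and 11.5% and 3.90% in i4g1 1 and 2. The half-width of the exact 95% interval was at most 0.0518 points in each of the 5 libraries with recovered reads. In limma its normalised count did not pass in ar21 (log2 fold change -1.74, adjusted p = 0.444) or in i4g1 (-3.86, adjusted p = 0.0674), though it passed in i4g1 without i4g1 1 (0.00225) or i4g1 2 (0.0451). A second entry of AT3G41768, at a mean of 28.7 in WT, was called lower in i4g1 (-1.68, adjusted p = 0.0287) but not in ar21 (-1.25, 0.109). The i4g1 call was lost without WT 2 (0.169), i4g1 1 (0.0545) or i4g1 2 (0.137), and the entry passed in ar21 without WT 1 (0.0460). Of the other reads, transcripts of the mitochondrial genome took 5.18% ± 0.770 (SD, n = 2) in WT, 1.37% ± 0.595 in ar21 and 0.394% ± 0.305 in i4g1. Transcripts of the plastid genome took 2.71% ± 0.541 in WT, 0.674% ± 0.208 in ar21 and 0.253% ± 0.185 in i4g1. Both shares take in every locus of these genomes, with organelle rRNA not set apart. In WT 2 the highest locus outside AT3G41768 was RRN26, by its symbol an organelle rRNA gene.

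**Figure D1:**
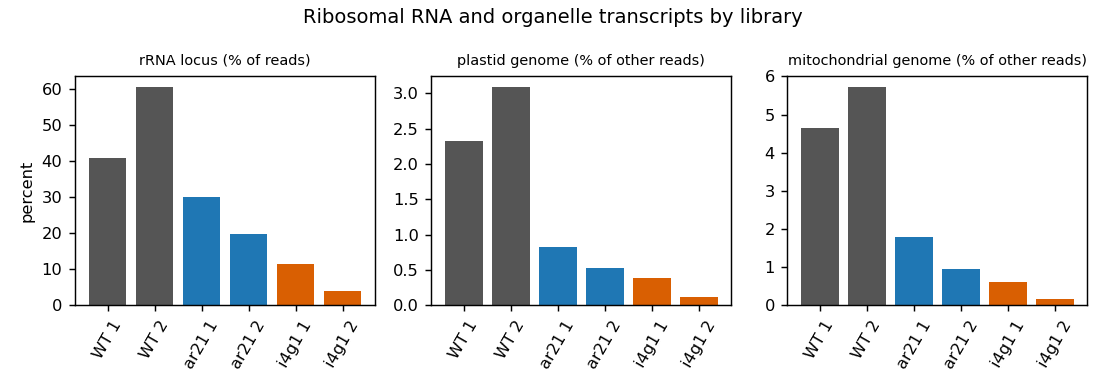
Bars show, for each of the 6 libraries, the percent of reads in the nuclear 18S rRNA locus (left) and the percent of the other reads from the plastid (middle) and mitochondrial (right) genomes. The rRNA share runs from 60.7% in WT 2 to 3.90% in i4g1 2, and both WT bars stand above the 4 mutant bars in each panel.

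The first comparison asks how the level of eIFiso4G1, a scaffold of a plant translation initiation complex, differs between the lines. eIFiso4G1 (AT5G57870, TAIR10.1 chromosome 5, 23439498 to 23443815, + strand) stood at 411 ± 60.5 in WT, 119 ± 5.25 in ar21 and 35.0 ± 14.9 in i4g1. The log2 fold change was -1.77 ± 0.24 in ar21 (SE, adjusted p = 0.000717) and -3.57 ± 0.24 in i4g1 (adjusted p = 8.97e-06), with all 4 mutant libraries below both WT libraries. The level was higher in ar21 than in i4g1 by a log2 difference of 1.80 (adjusted p = 0.0108). This call was lost without ar21 1 or ar21 2 (adjusted p up to 0.118) and with edgeR on 5 libraries (log2 difference 1.73). Its paralog eIFiso4G2 (AT2G24050, chromosome 2, 10225225 to 10228698, - strand) rose from 138 ± 4.94 in WT to 216 ± 21.5 in ar21, a log2 fold change of 0.64 with adjusted p = 0.0105, which was lost without ar21 1 or ar21 2 (adjusted p up to 0.130). In i4g1 it rose to 233 ± 17.78 (log2 fold change 0.75, adjusted p = 0.00297). EIF4G (AT3G60240, chromosome 3, 22261648 to 22268496, + strand), the scaffold of the other form of the complex, was at 1017 ± 40.6, 1110.0 ± 56.5 and 1142 ± 155 in WT, ar21 and i4g1, with adjusted p = 0.550 in ar21 and 0.391 in i4g1.

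**Figure D2:**
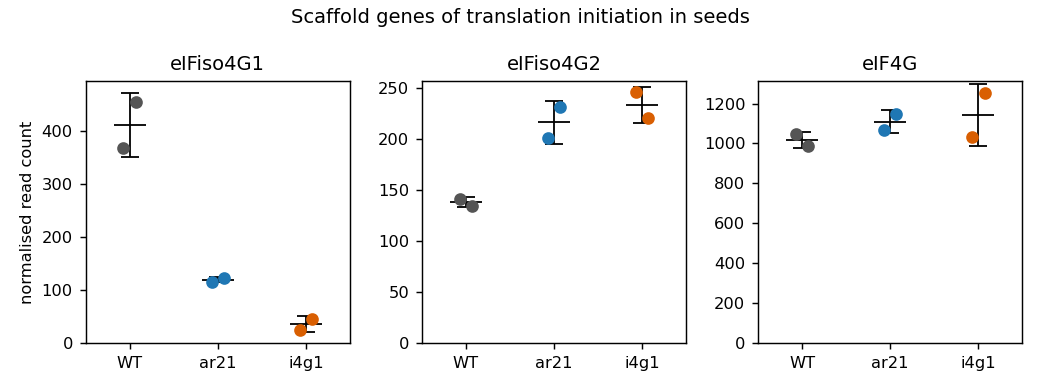
Points are the normalised counts of eIFiso4G1, eIFiso4G2 and eIF4G in each library, with the mean and SD of each line (n = 2). The eIFiso4G1 mean goes from 411 in WT to 119 in ar21 and 35.0 in i4g1, while eIFiso4G2 goes from 138 to 216 and 233.

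The second comparison asks which transcripts differ between ar21 and WT seeds. The receptor-like protein gene AtRLP55 (AT5G45770) rose from 17.7 ± 14.6 in WT to 497 ± 6.93 in ar21, and BXL1 (AT5G49360), a beta-xylosidase acting on cell wall polysaccharides, from 167 ± 37.5 to 1157 ± 152. Nuclear photosynthesis genes such as LHCB4.1 (AT5G01530), a light-harvesting protein of photosystem II, rose from 804 ± 23.3 to 2279 ± 47.6. GPT2 (AT1G61800), which imports glucose 6-phosphate into plastids, fell from 697 ± 150.2 to 138 ± 49.7, and HSP70 (AT3G12580), a chaperone, from 1219 ± 109 to 468 ± 67.4. In each of these genes both ar21 libraries stood on the same side of both WT libraries, and without WT 1 or WT 2 the log2 fold change of AtRLP55 was 4.103 or 5.91.

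Among the other genes with large changes in ar21, the log2 fold change was 4.16 for ATPMEPCRD (AT2G43050), annotated as a pectin methylesterase inhibitor, and 3.67 for the dormancy-associated gene AT2G33830. It was 3.33 for MLP28 (AT1G70830), 2.93 for AtGDU5 (AT5G24920), 2.90 for the peroxidase gene AT5G15180 and 2.75 for AT3G15450, with adjusted p from 1.22e-05 to 6.02e-05 over these genes. The lectin gene AT3G21380 fell from 460.4 ± 101 to 79.6 ± 42.2, and the neighbouring genes AT1G14940 and AT1G14930 from 854 ± 118 to 139.7 ± 52.6 and from 570.0 ± 97.2 to 109 ± 28.3. The plastid genes PSBA (ATCG00020) and PSAA (ATCG00350), which encode core proteins of the photosystems, fell from 19229.6 ± 16620.4 to 2182 ± 652 and from 11974 ± 46.9 to 2439 ± 878, and both calls were lost without ar21 2 (adjusted p = 0.0603 and 0.0695). Without WT 1 or WT 2 the values spanned 2.68 to 3.98 for MLP28, -5.43 to -1.002 for CUFF.2781.1 and -3.86 to -1.81 for PSBA. The call of AT4G05631 (log2 fold change -2.70) was lost without WT 1 or ar21 2 (adjusted p up to 0.0971). The assembled transcript CUFF.2781.1 (-3.22, WT 833 ± 1075) lost its call without WT 2, ar21 1 or ar21 2 (up to 0.238). Of the 82 plastid-encoded transcripts tested, 49 fell and 0 rose in ar21 (median log2 fold change -1.41), and of 25 mitochondrial ones 17 fell and 0 rose (median -1.60). The number that fell was 12 plastid and 4 mitochondrial without WT 2, 18 and 9 without ar21 1, and 2 and 2 without ar21 2, and it was 30 and 15 by edgeR and 4 and 7 by DESeq2. For rises, the count at an unadjusted p under 0.05 was also 0 in limma, as were the counts from edgeR and DESeq2.

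Of the 22 measured cytosolic ribosomal protein genes, 19 rose, 0 fell and 3 did not pass in ar21 (21 rose when adjusted over the list alone). Falls also numbered 0 at an unadjusted p under 0.05 in limma and 0 in edgeR and DESeq2, and the number that rose was 6 by edgeR, 7 by DESeq2, 6 without ar21 1 and 12 without ar21 2. The list had a median log2 fold change of 0.71 and camera gave adjusted p = 1.41e-14 (adjusted p = 0.542 with an estimated correlation). Examples are RPS2C (AT2G41840, 1290.5 ± 44.2 in WT, 2714 ± 167 in ar21) and EMB3010 (AT5G10360), known as RPS6B (1217 ± 64.7 and 2257 ± 78.4). Of 19 measured photosynthesis and chlorophyll genes, 14 rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone), with a median of 0.94 and adjusted p = 1.08e-11 (adjusted p = 0.542 with an estimated correlation). The number that rose was 9 without ar21 1, 9 by edgeR and 10 by DESeq2. PORB (AT4G27440), an enzyme of chlorophyll synthesis, rose from 116 ± 26.1 to 509 ± 72.2, LHCB5 (AT4G10340) from 1010.5 ± 155 to 2809 ± 395 and PSBO-1 (AT5G66570) from 1268 ± 72.4 to 2964 ± 128. The member that fell, named after its values were seen, was GLK2 (AT5G44190), a transcription factor of chloroplast development (log2 fold change -0.96), lost without WT 2, ar21 1 or ar21 2 (adjusted p up to 0.235). Between the same libraries the rRNA share was 50.7% ± 14.0 in WT and 24.9% ± 7.21 in ar21.

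The late embryogenesis and desiccation list was lower in ar21: 6 of 13 measured genes fell, 0 rose and 7 did not pass (7 fell adjusted over the list alone). The median was -0.54 and adjusted p = 0.00337 (adjusted p = 0.644 with an estimated correlation), and 3 fell without ar21 1, 4 by edgeR and 3 by DESeq2. LEA4-5 (AT5G06760) fell from 277 ± 47.4 to 115 ± 11.6, AT3G15670 from 4918 ± 441 to 2290.1 ± 283 and ATEM1 (AT3G51810) from 1244 ± 152 to 611 ± 58.3, all of them genes of late embryogenesis. At an unadjusted p under 0.05 the count of risers was 1 in limma, and edgeR and DESeq2 gave 0. Of 8 measured heat shock genes, 3 fell and 5 did not pass (3 fell adjusted over the list alone), with a median of -0.49 and adjusted p = 0.0107 (adjusted p = 0.542 with an estimated correlation). The call was lost without WT 1 (adjusted p = 0.123) or ar21 1 (0.120), and 1 gene fell without ar21 1, as by edgeR and by DESeq2. HSP70 had a log2 fold change of -1.39. ATHSP101 (AT1G74310, -0.70) was lost without ar21 1 (adjusted p = 0.102).

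Of 13 sugar starvation and SnRK1 marker genes, 6 rose and 7 did not pass in ar21 (6 rose adjusted over the list alone), with a median of 0.26, a mean of 0.77 and adjusted p = 0.00901 (adjusted p = 0.542 with an estimated correlation). The call was lost without WT 2 (0.0514), and 3 genes rose without ar21 1, 5 by edgeR and 2 by DESeq2. DIN10 (AT5G20250) rose from 386 ± 2.83 to 1234 ± 6.47, BGAL4 (AT5G56870) from 75.1 ± 23.1 to 326 ± 30.5 and ATTPS9 (AT1G23870) had a log2 fold change of 1.26. Of 13 genes of seed coat mucilage, 5 rose and 8 did not pass (6 rose and 1 fell adjusted over the list alone), with a median of 0.30 and adjusted p = 0.00901 (adjusted p = 0.542 with an estimated correlation). The call was lost without WT 1 (0.0751), and 3 genes rose without WT 1, ar21 1 or ar21 2, 3 by edgeR and 2 by DESeq2. The genes that rose include MUM2 (AT5G63800), a beta-galactosidase that modifies mucilage (13.3 ± 4.98 to 89.2 ± 5.34), GATL5 (AT1G02720, 227 ± 138 to 907 ± 45.1, log2 fold change 1.48 to 2.80 without WT 1 or WT 2) and the subtilase gene ARA12 (AT5G67360, 3409 ± 45.3 to 6238 ± 251).

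The lists closest to oil and reserve synthesis did not pass in ar21. Of 25 fatty acid synthesis genes 3 rose, 0 fell and 22 did not pass (3 rose adjusted over the list alone, median 0.12, adjusted p = 0.155). Falls numbered 1 at an unadjusted p under 0.05 in limma, 1 without WT 1, and 0 in edgeR and DESeq2. The genes that rose were LTA2 (AT3G25860, 0.54), CAC1 (AT5G16390, 0.63) and AT2G30200 (0.45), each lost without WT 1, ar21 1 or ar21 2 (adjusted p up to 0.215). Of 21 genes of triacylglycerol assembly and oil bodies 1 fell and 20 did not pass (1 fell adjusted over the list alone, median -0.06, adjusted p = 0.373), with 2 falling without i4g1 1 or i4g1 2. It was FAD3 (AT2G29980), the desaturase that makes linolenic acid (6695 ± 285 to 3985 ± 81.4), lost without WT 1, ar21 1 or ar21 2 (adjusted p up to 0.118). None of 7 storage protein genes passed (median -0.24, adjusted p = 0.290), and 1 was lower at an unadjusted p under 0.05 in limma, with 0 from edgeR and DESeq2 and 1 passing without i4g1 1 or i4g1 2. PAP85 (AT3G22640) was at 20930.0 ± 457 in WT and 23342 ± 499 in ar21, and SESA5 (AT5G54740) at 30437 ± 7094 and 21077 ± 1061. None of 15 starch genes passed (median -0.07, adjusted p = 0.290), with 1 lower at an unadjusted p under 0.05 in limma and 0 from edgeR and DESeq2.

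Among 13 seed maturation regulators 4 rose, 1 fell and 8 did not pass in ar21 (4 and 2 adjusted over the list alone, median 0.07, adjusted p = 0.880). DPBF2 (AT3G44460), the bZIP67 factor, fell from 829 ± 86.6 to 403 ± 17.1. MYB118 (AT3G27785, 0.80) rose, a call lost without ar21 1 or ar21 2 (adjusted p up to 0.0946), and of the regulators 1 rose without WT 2 and 0 without ar21 1 or ar21 2, where 2 fell without ar21 2. Of 13 abscisic acid genes 1 rose, 4 fell and 8 did not pass (1 and 5 adjusted over the list alone, median -0.30, adjusted p = 0.0622), with 2 falling without WT 1 and 1 without ar21 1 or ar21 2, and 0 rising without WT 1, ar21 1 or ar21 2. Of 14 genes of sucrose breakdown and plastid glycolysis 5 rose, 1 fell and 8 did not pass (5 and 4 adjusted over the list alone, median 0.12, adjusted p = 0.433), with 3 rising without either WT library and 2 without either ar21 library, and 2 falling without WT 1. The sugar transporter gene MTN3 (AT5G23660), known as SWEET12, rose from 300.0 ± 8.44 to 695 ± 0.771 and SUC5 (AT1G71890) had a log2 fold change of 1.98, while the sucrose synthase gene SUS3 (AT4G02280) fell from 756 ± 87.3 to 372 ± 6.08. In the eIF4F list 4 of 15 genes rose, 1 fell and 10 did not pass (4 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.193), with 2 rising without WT 1 and 1 without ar21 1 or ar21 2. EIF4A1 (AT3G13920), the helicase of the complex, rose from 958 ± 4.87 to 1673 ± 24.9. Of 11 genes of lipid breakdown MLS (AT5G03860), malate synthase, alone rose (261 ± 14.5 to 558 ± 3.58, median 0.01, adjusted p = 0.627), with 1 falling without WT 2, i4g1 1 or i4g1 2. Of 16 genes of the unfolded protein response 2 rose, 3 fell and 11 did not pass (3 and 3 adjusted over the list alone), with a median of 0.03 but a mean of -0.12 and a downward test (adjusted p = 0.739). The number that rose was 0 without WT 1, ar21 1 or ar21 2 and 1 without WT 2, and 1 fell without WT 2 or ar21 2. ATERDJ3A (AT3G08970), a chaperone of the endoplasmic reticulum, fell from 198 ± 22.1 to 79.3 ± 6.95.

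Of the cell type markers apart from mucilage, 2 of 10 seed coat flavonoid genes fell in ar21 (median 0.05, mean -0.02, a downward test, adjusted p = 0.626), with 1 without WT 1 and 0 without WT 2, ar21 1 or ar21 2. Of 5 markers of shoot tissue 1 rose and 1 fell (median -0.19, adjusted p = 0.626), with 0 rising without WT 2, ar21 1 or ar21 2 and 0 falling without WT 1, ar21 1 or ar21 2. None of 4 endosperm genes passed (2 rose adjusted over the list alone, median 0.59, adjusted p = 0.433), with 2 higher at an unadjusted p under 0.05 in limma and 0 from edgeR and DESeq2, and 1 rising without WT 2. ATEPR1 (AT2G27380), an extensin-like gene of the endosperm, was at 91354 ± 14207 in WT and 94562 ± 17674 in ar21. None of 3 measured defence genes passed (median -0.29, adjusted p = 0.626), with 1 lower at an unadjusted p under 0.05 in limma and 0 from edgeR and DESeq2, and 1 falling without i4g1 1 or i4g1 2.

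In all, limma called 2305 of 15591 genes in ar21 against WT, 1365 higher and 940 lower, of which 746 changed at least 2-fold. The count was 522 without ar21 1 and 827 without ar21 2, and 682 by edgeR and 365 by DESeq2 with 1 ar21 library. Camera called 6 of 20 lists, of which 0 passed with an estimated correlation (1 at an unadjusted p under 0.05). Fry called 5 lists, all higher, of which 4 were among these 6. The other was sucrose breakdown and plastid glycolysis (adjusted p = 0.0491 with fry). The 2 lower lists did not pass with fry, at 0.159 for late embryogenesis and 0.0605 for heat shock genes.

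The third comparison asks which transcripts differ between i4g1 and WT seeds. The plastid gene RBCL (ATCG00490), which encodes the large subunit of Rubisco, fell from 7447 ± 1562 to 395 ± 336, and PSAA, PSAB (ATCG00340) and PSBB (ATCG00680) had log2 fold changes of -4.53, -4.46 and -4.37. AT2G33830 rose from 6.46 ± 1.21 to 158 ± 27.6 and LHCB4.1 from 804 ± 23.3 to 2434 ± 32.7. The defence genes PR1 (AT2G14610), PR5 (AT1G75040) and BGL2 (AT3G57260, PR2), markers of salicylic acid responses, rose from 76.0 ± 32.2, 21.4 ± 14.5 and 16.3 ± 0.675 to 763 ± 644, 305 ± 265 and 181 ± 156. PR1 stood at 307.6 in i4g1 1 and 1218 in i4g1 2, both above the WT libraries. Without i4g1 1 or i4g1 2 the log2 fold changes spanned 2.07 to 4.05 for PR1, 2.05 to 4.08 for BGL2, -5.54 to -3.54 for RBCL, -5.55 to -3.50 for PSAA, -5.58 to -3.35 for PSAB and -5.51 to -3.23 for PSBB.

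Other genes with large changes in i4g1 were ECS1 (AT1G31580, log2 fold change 3.50), AtRLP55 (3.38), LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis (3.07), and AT3G15450 (2.97). AT4G05631, AT3G21380 and the mitochondrial gene ORF107A (ATMG00030) fell, with log2 fold changes of -5.20, -4.88 and -4.12. The assembled transcript CUFF.3847.5 was at 187 ± 251 in WT and 0.654 ± 0.311 in i4g1, a call lost without WT 2 (adjusted p = 0.0984). Leaving out WT 1, WT 2, i4g1 1 or i4g1 2 gave values of 2.57 to 4.63 for PR5, 2.54 to 4.46 for ECS1 and 2.14 to 3.998 for LOX2. Without WT 1 or WT 2 they were 2.48 to 4.28 for AtRLP55 and -7.80 to -2.71 for CUFF.3847.5, and without i4g1 1 or i4g1 2 -6.56 to -3.83 for AT4G05631 and -4.98 to -3.25 for ORF107A. Of the 82 plastid-encoded transcripts 74 fell and 0 rose (median -2.41), and of 25 mitochondrial ones 22 fell and 0 rose (median -3.13). For rises the count at an unadjusted p under 0.05 was also 0 in limma, and edgeR and DESeq2 gave 0.

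Of 19 nuclear genes of photosynthesis and chlorophyll, 18 rose and 1, again GLK2 (-1.09), fell in i4g1, also when adjusted over the list alone. The GLK2 call was lost without WT 2, i4g1 1 or i4g1 2 (adjusted p up to 0.117). The median was 1.21 and adjusted p = 1.85e-13 (adjusted p = 0.509 with an estimated correlation). PSBO-1 rose from 1268 ± 72.4 to 3339.9 ± 20.2, PORB from 116 ± 26.1 to 526 ± 142 and PSAE-1 (AT4G28750) from 214 ± 9.89 to 498 ± 4.92. Of 22 cytosolic ribosomal protein genes 18 rose, 0 fell and 4 did not pass (19 rose adjusted over the list alone). The median was 0.64 and adjusted p = 4.69e-10 (adjusted p = 0.509 with an estimated correlation), and falls also numbered 0 at an unadjusted p under 0.05 in limma and 0 in edgeR and DESeq2. RPS6 (AT4G31700) rose from 909 ± 188 to 2042 ± 124 and its paralog EMB3010 from 1217 ± 64.7 to 2459 ± 278. The rRNA share was 50.7% ± 14.0 in WT and 7.70% ± 5.37 in i4g1, and in the same libraries 2 of 5 shoot markers rose (1.78 for TGG2 (AT5G25980) and 2.71 for ATPP2-A1 (AT4G19840), with limits given with that list).

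In the late embryogenesis list 5 of 13 genes fell, 0 rose and 8 did not pass in i4g1 (5 fell adjusted over the list alone). The median was -0.46 and adjusted p = 0.0126 (adjusted p = 0.660 with an estimated correlation), a call lost without WT 1 (0.0763) or i4g1 2 (0.256), where 3 genes fell and 2 rose. With all libraries the rises also numbered 0 at an unadjusted p under 0.05 in limma and 0 in edgeR and DESeq2. LEA4-5 fell from 277 ± 47.4 to 108 ± 0.535 and AT3G15670 from 4918 ± 441 to 2186 ± 343. Of 8 heat shock genes 3 fell and 5 did not pass (4 fell adjusted over the list alone), with a median of -0.61 and adjusted p = 0.00928 (adjusted p = 0.509 with an estimated correlation), lost without WT 1 (0.0763). HSP70 fell from 1219 ± 109 to 474 ± 48.8 and ATHSP101 from 547 ± 69.0 to 332 ± 21.4. Of 13 sugar starvation genes 6 rose and 7 did not pass (7 rose adjusted over the list alone), with a median of 0.54 and adjusted p = 0.0122 (adjusted p = 0.509 with an estimated correlation). DIN10 rose from 386 ± 2.83 to 1306 ± 59.1, BGAL4 from 75.1 ± 23.1 to 355 ± 4.40 and DYL1 (AT1G28330) from 94.2 ± 18.4 to 201 ± 5.31. The 3 measured of 11 defence genes all rose, also adjusted over the list alone (median 3.07, adjusted p = 0.00649, and adjusted p = 0.509 with an estimated correlation).

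The oil and reserve lists did not pass in i4g1 either. Of 21 genes of triacylglycerol assembly 1 rose, 3 fell and 17 did not pass (0 and 3 adjusted over the list alone, median -0.15, adjusted p = 0.305), with 0 rising without any library except i4g1 2. FAD3 fell from 6695 ± 285 to 4061 ± 875 and AAPT2 (AT3G25585), an enzyme of phospholipid synthesis, from 766 ± 37.5 to 511 ± 12.9. Of 25 fatty acid synthesis genes 3 rose, 1 fell and 21 did not pass (3 and 1 adjusted over the list alone, median 0.04, adjusted p = 0.695), with 0 rising without WT 1 and 1 without i4g1 1. There 2 fell without WT 1 and 0 without WT 2, ar21 1, ar21 2 or i4g1 2. None of 7 storage protein genes passed (median -0.33, adjusted p = 0.457), with 1 lower at an unadjusted p under 0.05 in limma and 0 from edgeR and DESeq2. In i4g1 PAP85 was at 27369 ± 3931 and SESA5 at 21935 ± 5202, and 1 storage gene passed, as lower, without WT 1 or i4g1 1. Of 15 starch genes 2 rose, 2 fell and 11 did not pass (3 and 2 adjusted over the list alone, median 0.03, adjusted p = 0.716), with 1 rising without WT 1, ar21 1 or ar21 2 and 0 without WT 2 or i4g1 2. For falls the count was 1 without WT 1 and 0 without each of the other libraries.

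Among 13 seed maturation regulators 2 rose, 1 fell and 10 did not pass in i4g1 (3 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.723), with 0 rising without i4g1 1 and 1 without each other library. DPBF2 fell from 829 ± 86.6 to 448 ± 50.6. Of 13 abscisic acid genes 3 rose, 4 fell and 6 did not pass (3 and 6 adjusted over the list alone), with a median of -0.35 but a mean of 0.14 and a downward test (adjusted p = 0.457), and 2 fell without i4g1 1. NCED6 (AT3G24220), an enzyme of abscisic acid synthesis, rose from 161 ± 25.9 to 293 ± 1.76 and ATPP2CA (AT3G11410), a phosphatase that restrains the response, fell from 503 ± 4.99 to 312 ± 29.6. Of 14 genes of sucrose breakdown and plastid glycolysis 4 rose, 4 fell and 6 did not pass (6 and 4 adjusted over the list alone, median 0.06, adjusted p = 0.723), with 2 falling without WT 2. MTN3 rose from 300.0 ± 8.44 to 757 ± 48.9 and SAG29 (AT5G13170), known as SWEET15, from 4227 ± 18.1 to 7073 ± 382, while SUS3 fell from 756 ± 87.3 to 252 ± 28.7. In the eIF4F list 4 of 15 rose, 2 fell and 9 did not pass (6 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.310), with 2 rising without i4g1 1 and 1 falling without any library except WT 2. Of 11 genes of lipid breakdown 2 rose, 1 fell and 8 did not pass (median 0.03, adjusted p = 0.723), with 1 rising without WT 2 or i4g1 1 and 2 falling without WT 2, and MLS rose to 423 ± 37.8. Of 16 genes of the unfolded protein response 5 rose, 2 fell and 9 did not pass (median 0.10, adjusted p = 0.457), with 3 rising without WT 1 or i4g1 2. The disulfide isomerase genes ATPDIL1-2 (AT1G77510) and ATPDIL1-1 (AT1G21750) rose from 832 ± 30.7 to 1389 ± 34.4 and from 3734 ± 9.54 to 6454 ± 876.

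Among the cell type markers, 3 of 10 seed coat flavonoid genes fell in i4g1 (median -0.21, adjusted p = 0.187), and 1 fell without WT 2, ar21 1 or ar21 2. TT5 (AT3G55120), chalcone isomerase, fell from 91.6 ± 20.9 to 34.4 ± 6.94. Of 13 mucilage genes 5 rose, 1 fell and 7 did not pass (6 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.121), with 3 rising without WT 1 and 0 falling without any library except WT 1, and the log2 fold change of MUM2 was 2.32. Of 5 markers of shoot tissue 2 rose (median 0.01, mean 0.85, adjusted p = 0.457), of which the phloem gene ATPP2-A1 went from 5.67 ± 4.05 to 38.5 ± 2.35, with log2 fold changes of 2.05 to 3.38 without WT 1 or WT 2. TGG2, a myrosinase of leaf cells, went from 18.6 ± 6.48 to 78.4 ± 64.0 (log2 fold change 0.85 to 2.71 without i4g1 1 or i4g1 2), lost without WT 2 or i4g1 2 (adjusted p up to 0.330). None of 4 endosperm genes passed (2 rose adjusted over the list alone, median 0.61, adjusted p = 0.422), with 2 higher at an unadjusted p under 0.05 in limma and 0 from edgeR and DESeq2, and 1 rising without WT 2.

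In all, limma called 3489 genes in i4g1 against WT, 1952 higher and 1537 lower, of which 1179 changed at least 2-fold. The count was 2046 without i4g1 1 and 2269 without i4g1 2, and 1285 by DESeq2. Camera called 6 lists, of which 0 passed with an estimated correlation (0 at an unadjusted p under 0.05). Fry called 0 of the 20 lists (8 of the 20 at an unadjusted p under 0.05).

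**Figure D3:**
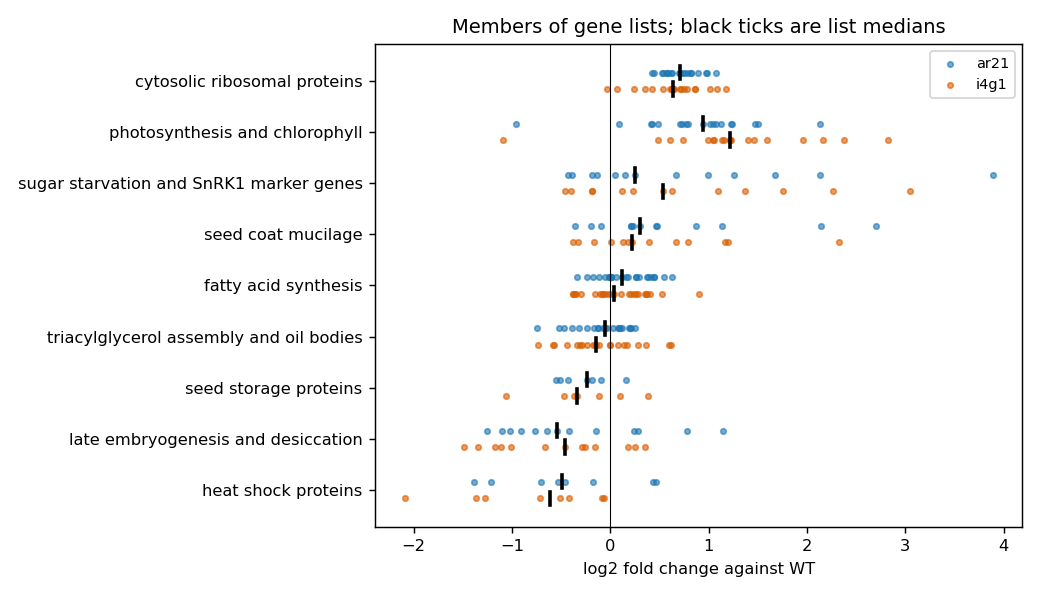
Each point is the log2 fold change against WT of 1 measured member of 9 gene lists, in ar21 (blue) and i4g1 (orange), and black ticks are list medians. Ribosomal protein medians are 0.71 and 0.64, photosynthesis medians 0.94 and 1.21, and late embryogenesis medians -0.54 and -0.46, while fatty acid synthesis stands at 0.12 and 0.04.

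The fourth comparison asks how far the changes in ar21 and i4g1 coincide. Besides AT2G33830 and AtRLP55, the assembled transcript CUFF.1017.1 rose in both mutants (1.83 ± 2.59 in WT, 50.5 ± 3.16 in ar21, 50.3 ± 6.72 in i4g1), with log2 fold changes of 3.46 to 5.68 in ar21 and 3.46 to 5.67 in i4g1 without WT 1 or WT 2. So did HIPP25 (AT4G35060), a gene annotated for metal transport, which was listed at 0 in both WT libraries and at 19.2 ± 5.47 and 16.3 ± 7.78 in ar21 and i4g1. The sugar transporter gene STP14 (AT1G77210) was at 10.4 ± 14.7, 67.2 ± 14.3 and 50.3 ± 5.48 in WT, ar21 and i4g1, called in both mutants but lost without either library of the mutant (adjusted p up to 0.147 in ar21 and 0.0999 in i4g1). Without WT 1 or WT 2 its log2 fold change was 1.64 to 6.08 in ar21 and 1.24 to 5.68 in i4g1, and that of PSBA in i4g1 was -5.03 to -2.98 without either WT or i4g1 library. Among shared falls were PSBA (to 1087 ± 751 in i4g1), AT1G14940 (to 117 ± 23.4), AT3G21380, AT4G05631 and AT3G28170, which was at 46.6 ± 6.50 in WT, 5.71 ± 1.87 in ar21 and 0.437 ± 0.618 in i4g1. The ar21 calls of AT3G28170 (without ar21 1 or ar21 2, adjusted p up to 0.0891), PSBA (without ar21 2, 0.0603) and AT4G05631 (without WT 1 or ar21 2, up to 0.0971) were lost with 1 library left out.

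In all, 1133 genes were called higher in both mutants, beside 170.9 for independent lists of these sizes and 0 in simulations of unchanged groups that share the WT libraries. Another 758 were called lower in both, beside 92.7 and 0. The simulated value leaves out real effects, so it is near 0 at this threshold by its design, and the value for independent lists leaves out the shared WT libraries. The counts of genes called in both mutants were 382 and 249 by edgeR, 324 and 170 without ar21 1, and 508 and 229 without ar21 2. No gene was called in opposite directions by limma (0, with 14 at an unadjusted p under 0.05 in both), nor by edgeR (0) or DESeq2 (0). Across the 15591 genes, which are not independent replicates, the log2 fold changes of ar21 and i4g1 had r = 0.830 and rho = 0.831, beside 0.5001 and 0.466 in the simulations, and a covariance of 0.316 beside 0.0370. The simulations gave all libraries the same spread for a gene. The replicate correlation was lowest in WT (0.957, beside 0.983 in ar21 and 0.974 in i4g1). Noisier shared WT libraries would raise the simulated values, so the size of the excess over them is not known. With each mutant set against a different single WT library, r was 0.527 and 0.571 and the covariance 0.238 and 0.255. The mean of both mutants differed from WT in 3802 genes, 2123 higher and 1679 lower, with 2253 without ar21 1, and 2301 by edgeR and 1114 by DESeq2.

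**Figure D4:**
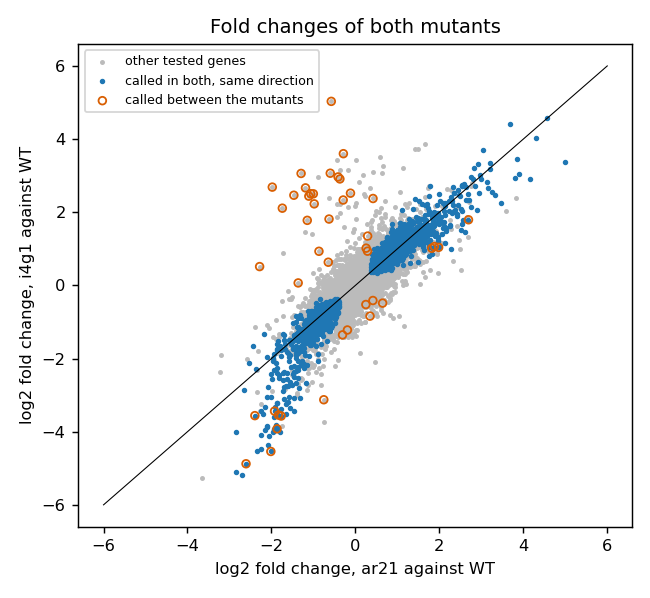
Each point is 1 of 15591 genes, with its log2 fold change against WT in ar21 (x axis) and i4g1 (y axis), blue where called in both in the same direction and ringed in orange where called between the mutants. The line marks equal values, and r across genes is 0.830.

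The last comparison asks which transcripts differ between the mutants themselves. Among the genes called higher in i4g1, PR1 stood at 30.1 ± 11.5 in ar21 and 763 ± 644 in i4g1, PR5 at 15.9 ± 5.93 and 305 ± 265, and LOX2 at 15.5 ± 4.93 and 249 ± 201. COR15A (AT2G42540), a cold-regulated chloroplast protein, stood at 21.5 ± 0.608 and 392 ± 311, and CA2 (AT5G14740), a carbonic anhydrase, at 8.59 ± 4.90 and 125 ± 98.5. The log2 differences, ar21 minus i4g1, were -4.35 for PR1, -3.89 for PR5, -3.85 for COR15A, -3.67 for LOX2 and -3.55 for CA2, with adjusted p from 0.00685 to 0.0166. Without i4g1 1 or i4g1 2 they spanned -5.35 to -3.36 for PR1, -4.91 to -2.86 for PR5, -4.77 to -2.94 for COR15A, -4.60 to -2.73 for LOX2 and -4.45 to -2.65 for CA2. In i4g1 2 the level of each of these 5 genes was higher than in i4g1 1. Of the plastid transcripts 1 of 82 and of the mitochondrial ones 3 of 25 were called higher in ar21 (0 and 0 by edgeR and DESeq2). The count was 0 plastid transcripts without any library except i4g1 1, where it was 50, and for mitochondrial ones it was 2 without WT 1 or WT 2, 0 without ar21 1 or i4g1 2, 1 without ar21 2 and 13 without i4g1 1. Named among them are log2 differences of 2.53 for RBCL (adjusted p = 0.0426), 2.06 for COX2 (ATMG00160, 0.0344) and 1.71 for ORF25 (ATMG00640, 0.0421), with RBCL at 1.52 to 3.53 without i4g1 1 or i4g1 2. The rRNA share was 24.9% ± 7.21 in ar21 and 7.70% ± 5.37 in i4g1. The lectin gene AT3G21380 was also higher in ar21 (2.27, 0.0108).

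Each of these calls was lost in some fit with 1 library left out. PR1 was lost without ar21 2 (adjusted p = 0.0785), COR15A without ar21 1 or ar21 2 (up to 0.101), and PR5, LOX2, CA2 and COX2 without ar21 1, ar21 2 or i4g1 2 (up to 0.177, 0.285, 0.189 and 0.453). AT3G21380 was lost without ar21 1 or i4g1 2 (up to 0.114), and RBCL and ORF25 without any library except i4g1 1 (up to 0.454 and 0.505).

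**Figure D5:**
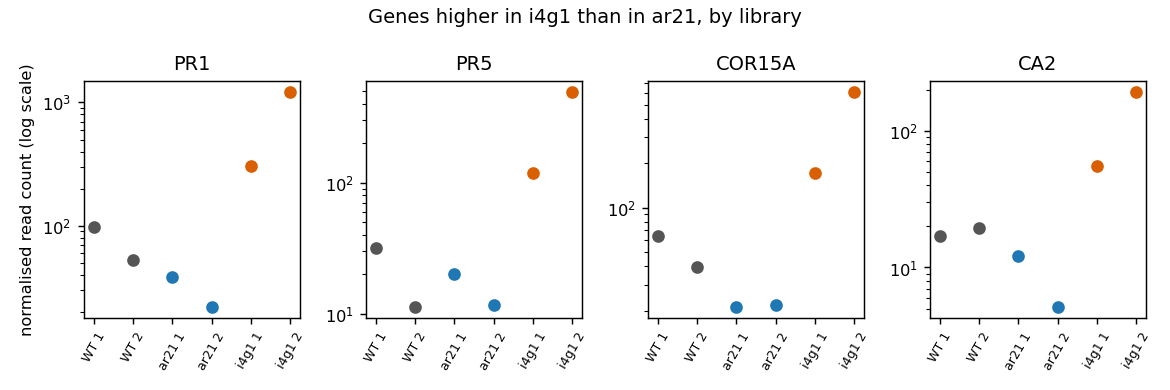
Points are the normalised counts of PR1, PR5, COR15A and CA2 in each library on a log axis. The PR1 counts in i4g1 1 and 2 are 307.6 and 1218, against a mean of 30.1 in ar21 and 76.0 in WT.

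Camera called 5 lists between the mutants. The defence list was lower in ar21 than in i4g1, with 2 of 3 measured genes passing (3 adjusted over the list alone, 1 without ar21 1 or i4g1 2 and 0 without ar21 2), a median of -3.89 and adjusted p = 1.95e-08 (adjusted p = 0.595 with an estimated correlation). Of 5 shoot markers 1, TGG2 (-2.93), was lower in ar21 (2 adjusted over the list alone), with a median of -0.40 and adjusted p = 0.0150 (adjusted p = 0.595 with an estimated correlation), lost without i4g1 2 (0.173). In the photosynthesis list 1 of 19 genes, RBCS-3B (AT5G38410, -1.96), passed (3 adjusted over the list alone, 2 without WT 1, WT 2 or i4g1 1 and 0 without ar21 1, ar21 2 or i4g1 2), with a median of -0.10 and adjusted p = 0.00800 (adjusted p = 0.816 with an estimated correlation), lost without ar21 2 (0.220) or i4g1 2 (0.268). In the starch list 1 of 15, the beta-amylase gene CT-BMY (AT4G17090, -2.44), passed, with a median of -0.07 and adjusted p = 0.0129 (adjusted p = 0.595 with an estimated correlation), lost without ar21 1 (0.161) or i4g1 2 (0.268). None of 16 genes of the unfolded protein response passed in limma (1 higher and 4 lower at an unadjusted p under 0.05, 0 in edgeR and DESeq2), with a median of -0.20 and adjusted p = 0.00800 (adjusted p = 0.595 with an estimated correlation), lost without ar21 1 (0.116) or i4g1 2 (0.173). The calls of TGG2, RBCS-3B and CT-BMY were lost without ar21 1, ar21 2 or i4g1 2 (adjusted p up to 0.453, 0.177 and 0.403), and that of TGG2 also without WT 1. Without i4g1 1 or i4g1 2 the differences spanned -3.86 to -1.99 for TGG2 and -3.26 to -1.62 for CT-BMY.

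In the other 15 lists camera made no call between the mutants, and the signs differed in 6 of them. Of their members eIFiso4G1 (1.80) in the eIF4F list and COR15A (-3.85) in the abscisic acid list passed, each count falling to 0 without ar21 1 or ar21 2 and the latter rising to 2 without i4g1 1. The median, the mean and the direction of the test were -0.03, 0.09 and upward for eIF4F genes, 0.07, 0.22 and downward for late embryogenesis genes, 0.04, -0.08 and downward for endosperm genes, and 0.05, -0.01 and upward for triacylglycerol genes. They were -0.07, 0.00 and downward for storage protein genes and -0.08, 0.01 and downward for sugar starvation genes. In all, limma called 44 genes between the mutants, 18 higher and 26 lower in ar21, with 2 without ar21 1, 3 without ar21 2, 6 without i4g1 2 and 158 without i4g1 1, and 2 by edgeR and 7 by DESeq2. Fewer lists were called without ar21 1 or i4g1 2, and those called without i4g1 2 were not all among the 5. Of the 5 lists 0 passed with an estimated correlation (1 at an unadjusted p under 0.05, the defence list) and 0 with fry. Over all 20 lists, fry gave an unadjusted p under 0.05 for 3. Of these, defence (0.0345) was among the 5 lists, while sucrose breakdown and plastid glycolysis (0.00731) and seed coat flavonoid (0.0149) were not.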

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

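All tests of an explanation in this part were chosen after the results they address had been seen, while the test of ar21 against i4g1 was planned. That test gave 44 genes and 5 lists that differ between the mutants, and no library could be tested as an outlier in groups of 2. The log2 differences below are ar21 minus i4g1.

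Among the genes called higher in i4g1 were some of defence and of leaf cells, with -4.35 for PR1, -3.89 for PR5, -3.85 for COR15A, -3.67 for LOX2, -3.55 for CA2 and -2.93 for TGG2, and list medians of -3.89 for defence (2 of 3 passing) and -0.40 for shoot tissue (1 of 5 passing), each with adjusted p = 0.595 with an estimated correlation. RNA of another source in the i4g1 libraries may explain these, and it would add the genes in 1 proportion per library. The excess over ar21 in i4g1 2 was a median of 3.87 times that in i4g1 1 over 26 nuclear genes (range 0.884 to 4.88, 17 of 26 within 1.5-fold of the median), and the log2 ratio had an SD of 0.825. These genes were chosen for the pattern and a stronger defence response in i4g1 2 would give a like ratio, so 1 added source and a response of the seeds cannot be told apart. Leaf tissue as that source also stays open, since the photosynthesis list had a median log2 ratio of i4g1 2 to i4g1 1 of 0.15 (SD 0.457, 14 of 19 higher in i4g1 2), while these 19 genes are also measured in WT seeds (LHCB5 at 1010.5 ± 155).

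The other differences were 1.80 for eIFiso4G1, 2.53 for RBCL, 2.06 for COX2, 1.71 for ORF25 and 2.27 for AT3G21380, beside an rRNA share of 24.9% in ar21 and 7.70% in i4g1. The remaining genes gave -2.44 for CT-BMY and -1.96 for RBCS-3B, and the list medians were -0.072 for starch, -0.10 for photosynthesis and -0.20 for the unfolded protein response. Each of these genes lost its call with some library left out, as did these 3 lists, with the libraries and values given in the last comparison.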

How the results depend on the processing

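Of the settings here, nuclear genes only, 4 libraries, the length and GC correction and edgeR on thinned reads were chosen after seeing the data, and the others were planned. Genes called in ar21 numbered 2305, but 675 with no trend, 682 with edgeR, 365 with DESeq2, 950 at adjusted p under 0.01, 746 at 2-fold or more, 3710 with 4 libraries (WT 2 and i4g1 2 left out) and 522 to 2377 with 1 library left out. In i4g1 they numbered 3489, but 1778 with no trend, 1285 with DESeq2, 1655 with edgeR on thinned reads, 1645 at adjusted p under 0.01, 1179 at 2-fold or more and 2046 to 3183 with 1 library left out. For the mean of both mutants they numbered 3802, but 2308 with no trend, 2301 with edgeR, 1114 with DESeq2, 1911 at adjusted p under 0.01, 1008 at 2-fold or more and 2253 to 3362 with 1 library left out. Between the mutants 44 were called, but 2 with no filter, 0 with no trend (1167 at an unadjusted p under 0.05), 2 with edgeR, 7 with DESeq2, 3 at adjusted p under 0.01, 666 with 4 libraries and 2 to 158 with 1 library left out. The edgeR and DESeq2 fits hold 1 ar21 library, and the cause of these shifts was not tested.

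Lists called with an estimated correlation numbered 0 in ar21, 0 in i4g1 and 0 between the mutants, and fry called 0 in i4g1 and 0 between the mutants, with unadjusted counts in the report. Camera with an estimated correlation has 3 residual degrees of freedom here, so its counts of 0 do not show that the lists are unchanged. Between the mutants the 5 lists became 3 at a filter of 50 and 9 with quantile normalisation. The number also moved with 4 libraries and with 1 library left out. Without i4g1 2 the lists called were not all among the 5. At a filter of 50 the calls of late embryogenesis (0.0527) and sugar starvation (0.0579) in i4g1 and of photosynthesis between the mutants (0.0711) were lost. Over 17 list calls, 237 of 288 values under other settings passed in the same direction and 51 did not pass. Of 3668 values for 283 results on named genes, 3312 had the same call and direction, 317 no longer passed, 39 newly passed and 0 changed direction (a count over settings, with no test of its own). With 1 library left out, 40 of 72 called named genes in ar21, 61 of 84 in i4g1 and 0 of 13 between the mutants passed in all 6 fits, and each kept its direction. The difference in eIFiso4G1 between the mutants was 1.73 with edgeR (adjusted p = 0.0810) and 1.37 to 2.24 with 1 library left out. The correlation of the mutants was 0.830, but 0.757 with no filter, 0.866 at a filter of 50, 0.527 and 0.571 with separate WT libraries and 0.784 to 0.869 with 1 library left out. Part of its excess over 0 may come from the shared WT libraries, and splitting them leaves 1 WT library per mutant. With the length and GC correction the calls were 1126 higher and 1050 lower in ar21, 1576 and 1577 in i4g1 and 1807 and 1795 for the mean, so higher and lower calls are closer in number than the 1365 and 940, 1952 and 1537, and 2123 and 1679 without it. Leaving out 1 library moved the fold change by over 1.5-fold in 9 of 72 called named genes in ar21, 22 of 84 in i4g1 and 8 of 13 between the mutants. Other scalings moved the median of all genes by less than 0.02 (log2).

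With the replicate number as a block the calls were 2456 in ar21, 3674 in i4g1, 3957 for the mean and 81 between the mutants. The deviations of libraries with the same number had correlations of -0.0803, -0.0277 and 0.125, and the labels do not say that a number marks a shared batch.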

Other observations

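All tests in this part were chosen after the results were seen, the terms of biological processes included. Some histone genes were higher in both mutants. The histone H3 gene AT1G09200 stood at 23.57 ± 2.31 in WT, 61.7 ± 13.7 in ar21 and 56.8 ± 4.90 in i4g1, and the linker histone gene AT2G30620 at 620.1 ± 85.0, 1075 ± 35.2 and 1113 ± 230.0 (n = 2 per line). For the mean of both mutants the log2 fold change was 1.29 ± 0.21 (SE, adjusted p = 0.00127) and 0.82 ± 0.13 (adjusted p = 0.000954). The linker-type gene AT3G18035 (0.65 ± 0.10, adjusted p = 0.000926) and the histone H2B gene AT5G59910 (0.71 ± 0.13, adjusted p = 0.00217) rose as well. These 4 genes, named after their values were seen, had adjusted p of at most 0.0129 in ar21 and 0.00436 in i4g1 (AT5G59910 and AT1G09200), and for the mean passed in all 6 fits with 1 library left out. Of the 46 measured genes of nucleosome assembly 25 rose and 21 did not pass for that mean (median 0.64, adjusted p = 1.56e-09, and adjusted p = 0.656 with an estimated correlation). In ar21 and in i4g1 20 rose, with adjusted p = 1.18e-10 and 1.55e-07 (0.634 and 0.735 with an estimated correlation).

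Of 343 genes annotated for translation 210 rose and 8 fell (median 0.59), of 96 for ribosome biogenesis 71 rose and 25 did not pass (median 0.61), and of 108 for the response to cold 52 rose and 6 fell (median 0.44). The number that fell for translation was 4 without WT 1 or ar21 2 and 5 without ar21 1. The adjusted p was 2.62e-25, 6.30e-21 and 9.56e-07 for these terms, and adjusted p = 0.701, 0.656 and 0.656 with an estimated correlation. Of 52 annotated for apoptosis 11 fell and 41 did not pass (median -0.25, adjusted p = 0.00548, and adjusted p = 0.769 with an estimated correlation). The number that fell was 7 without WT 1, 6 without ar21 1 or i4g1 1 and 5 without ar21 2. Of the 140 terms camera called 16 for the mean, 15 in ar21 and 20 in i4g1. With an estimated correlation 0 of the 140 passed in each (6, 5 and 7 of the 140 at an unadjusted p under 0.05).

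Plastid and mitochondrial transcripts fell in both mutants, 49 of 82 and 17 of 25 in ar21 (2 and 2 without ar21 2, 18 and 9 without ar21 1, 12 and 4 without WT 2) and 74 and 22 in i4g1, while the calls of the rRNA locus depend on the entry and on single libraries, as given at the start of the report. The falls were not confined to plastid transcripts, since mitochondrial transcripts had a median of -3.13 in i4g1 (SD 0.966). That median restates the pattern and tests no cause, so a plastid change beside a fall of both is not excluded. More RNA without poly(A) carried into some libraries is a candidate explanation: in 6 of 6 comparisons within replicate pairs, the library with the higher rRNA share had the higher organelle sum. The plastid and the mitochondrial sum were each compared in every pair and moved together, so the 6 comparisons are not independent. Organelle rRNA was not taken out of these sums, so part of each comparison may set rRNA against rRNA. A lower organelle content of the mutant seeds was not tested.

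The lists of ribosomal protein and photosynthesis genes were called higher and those of late embryogenesis and heat shock genes lower in both mutants. None passed in camera with an estimated correlation (adjusted p from 0.509 to 0.660), a test with 3 residual degrees of freedom and little power here. The heat shock calls were also lost without WT 1 in both mutants and without ar21 1 in ar21. The i4g1 call of late embryogenesis was lost without WT 1 or i4g1 2. In every replicate pair, ribosomal protein genes were lower in the library with the lower rRNA share. The mean difference, lower minus higher rRNA share, was -0.196 (-0.24 to -0.16), beside 0.67 in the mutants. This argues against rRNA share or depth as the whole cause for these genes. It does not exclude it, since replicates may differ in other ways and the share also parts WT from mutant libraries. For photosynthesis (mean -0.0304, -0.23 to 0.35), late embryogenesis (0.0657, -0.52 to 0.41) and heat shock genes (0.405, -0.07 to 0.69) the pairs went both ways, so for these lists rRNA share or depth and an effect of the lines cannot be told apart. Of 5 shoot markers 2 rose in i4g1, and 1 rose and 1 fell in ar21. Whether shoot tissue plays a part in the photosynthesis rise was not tested. After correction for transcript length and GC content, 8 of 8 list calls at the preset correlation passed in the same direction. This argues against these properties as the whole cause. The correction removes only a smooth trend in each library, so a part played by them is not excluded. Younger seeds in the mutants may also give such changes and cannot be told apart from an effect of the lines, because the storage list (median -0.33 in i4g1) has members that move both ways and no series of seed ages was analysed here.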
